A study of Homo sapiens with 6 samples.

How the data were processed

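The study holds 6 ChIP-seq libraries from LNCaP cells: H3T11P, WDR5 and input, each with vehicle or with 10 nM R1881 for 3 h, with 1 library per group. Per the labels' protocols, chromatin was cross-linked with formaldehyde and sonicated, and libraries were made with a KAPA kit. The 4 peak lists of the H3T11P and WDR5 libraries were analysed, and the reads of the inputs entered only through the input tags that the lists give per peak. Bowtie 0.12.9, HOMER and hg18 are named in the submitters' processing notes. Read trimming and the handling of reads with several matches are not given in the sources used here.

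Per the file headers, each list was called by HOMER findPeaks on a single library against the input of the same treatment, with at most 1 tag considered per bp, at least 4-fold over input and a p over input of at most 1e-04. H3T11P was called in histone style (peaks of 500 bp or more, stitched into regions, Poisson threshold 0.001, with 0 peaks removed by the local filter). WDR5 was called in factor style (fixed peaks of 200 bp with vehicle and 218 bp with R1881, false discovery rate 0.001, at least 4-fold over the surrounding 10 kb). Peak numbers of the 2 antibodies are therefore not comparable. The tag thresholds were 12 and 11 tags for H3T11P with vehicle and R1881, and 11 and 13 for WDR5, so thresholds differed relative to depth. The file headers give 10000000 as the total to which the authors scaled the normalised tag count, a signal value. The deposited tag count of each peak is a whole-number count in 3 lists and is scaled to the input library in the R1881 WDR5 list. Deposited with each peak are also a peak score, a fold or ratio over input, a p-value over input and, for WDR5, a focus ratio, a fraction of tags on the strand side expected around a peak centre. The values of a peak were used to describe, rank or filter peaks within its own list. Height stands for the normalised tag count, which for H3T11P is a total over a region of variable length. Where values from lists of both treatments stand side by side, they are the authors' values, and no change is read from them.

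Depth was 14513992 (vehicle) and 12138666 (R1881) tags for H3T11P, and 11895353 and 17764495 tags for WDR5, per the file headers. The steps of the scaled input tags put the inputs at about 14900000 tags with vehicle and 15800000 with R1881. A peak typically rests on few tags, with a median of 8.3 to 10.1 normalised tags in the 4 lists, so peaks near the threshold are sensitive to chance. Reads lack molecular identifiers, so intervals cover counting error only, and they do not cover variation between cultures.

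Overlaps of at least 1 bp were counted with bedtools 2.31.1 on the coordinates as deposited. Chance overlap was described by moving 1 list around each chromosome, within the span covered by all lists, 1000 times. Such shifts keep spacing and lengths but not gene density, so local shifts of 50 to 500 kb per peak were run too. Exact binomial intervals (95%) were computed with scipy 1.17.1, tables with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures with matplotlib 3.10.9. On simulated data with 1000 peaks and 300 planted overlaps, 300 were recovered, and uniform placement gave a mean of 4.24 chance hits where 3.99 follow from theory.

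Before the data were examined, the sites to be named were fixed as the 3 peaks with the highest normalised tag count per list, and the 10 R1881-only joint sites with the highest WDR5 tag count. The alternatives fixed then were at least 8-fold over input, a common minimum tag count (5.8 for H3T11P, 6.7 for WDR5), leaving out unplaced contigs, merging peaks within 1 kb, an overlap of 50% of the shorter peak, centres within 1 kb, and uniform placement. Alternatives chosen after seeing the data were a common peak score per 10000000 tags (9.06 for H3T11P, 9.25 for WDR5), thinning of the deeper library's peak scores with 100 draws, a p over input of at most 1e-10, local shifts, and leaving out the vehicle H3T11P list. The planned promoter shares and gene lists, and the planned naming of genes, were not run, because the peak lists name no genes and the gene table used here is of another build than hg18. The 1 Mb windows were ranked after the lists were read.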

Results

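Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 phosphorylated at threonine 11 (H3T11P) and the protein WDR5 in LNCaP cells, an androgen-responsive human prostate adenocarcinoma line that carries androgen receptor. WDR5 is a WD40-repeat subunit shared by the MLL and SET1 complexes that methylate lysine 4 of histone H3. Cells received 10 nM R1881, a synthetic androgen, or ethanol vehicle for 3 h, and each antibody and each input was sequenced as 1 library per treatment. The H3T11P libraries held 14513992 tags with vehicle and 12138666 with R1881, and the WDR5 libraries held 11895353 and 17764495. As there were no replicates, no test between treatments was possible. The intervals given are 95% exact binomial (Clopper-Pearson) intervals over peaks, and they cover counting error only. Positions are on hg18.

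The first comparison asked where H3T11P was found with and without androgen. The R1881 list held 16677 H3T11P peaks and the vehicle list 2612, a ratio of 6.38. Within the R1881 list, 1921 peaks (11.5%) carried 20 or more normalised tags (the authors' values, scaled to 10000000 tags per library), and within the vehicle list 7 (0.268%) did. Regions of 1 kb or longer numbered 1496 with R1881 and 6 with vehicle. The R1881 list covered 10.6 Mb at a mean of 20.4 normalised tags per kb, and the vehicle list 1.34 Mb at 16.7. In the headers, peaks took 2.17% of all tags with R1881 and 0.22% with vehicle.

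The 2 H3T11P lists shared few positions. An R1881 peak overlapped 60 of the 2612 vehicle peaks (2.3%, interval 1.76 to 2.95), and these made up 0.36% (0.275 to 0.463) of the R1881 list. Moving the R1881 list along each chromosome 1000 times gave a mean of 19.5 overlaps and at most 34, and local shifts of 50 to 500 kb gave a mean of 31.7 and at most 51. Recurrence was 2.3% in the lowest quintile of vehicle peaks by tag count and 3.06% in the highest. Heights in this list differed little, with quintiles 1 to 4 running from 5.5 to 9.0 normalised tags, so these shares say little on height. Most vehicle peaks (83.8%) lay within 1 tag of the caller's threshold, against 57.8% of R1881 peaks. The R1881 library was the shallower one, and the ratio of list lengths was 12.0 after the vehicle peaks were thinned to its depth, 12.0 at a p over input of at most 1e-10 and 39.5 at a common peak score per 10000000 tags. The thinning and the common score removed vehicle peaks only, so they could only raise this ratio. Recurrence was 0.329% (3 of 912) among peaks at least 8-fold over input, where local shifts gave a mean of 2.29 overlaps and 387 of 1000 were at least as high, and 1.53% when 50% of the shorter peak had to overlap.

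**Figure D1:**
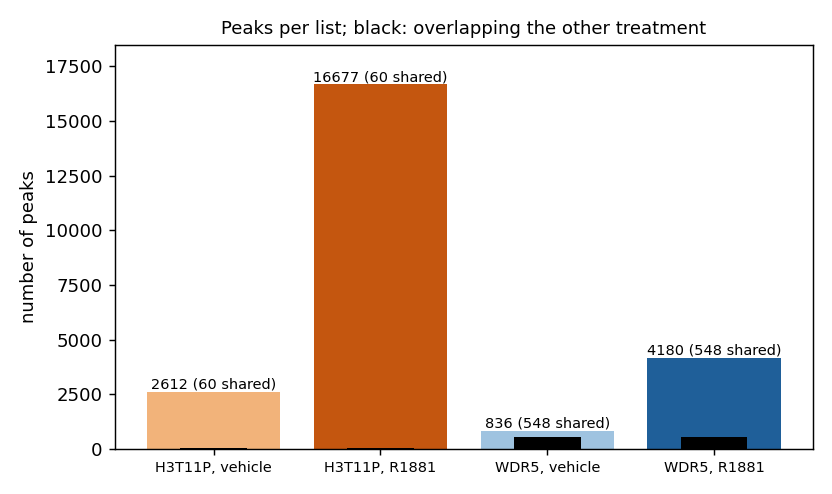
Number of peaks in each of the 4 lists (vertical axis, peaks), with the peaks that overlap the same antibody's list from the other treatment in black. Of the H3T11P peaks 60 were shared between treatments, and of the WDR5 peaks 548.

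The H3T11P regions with the highest tag counts were taken from each list separately, and no change between treatments is read from their ranks. With vehicle, the highest tag count stood at chromosome 17, 59347570 to 59348609, with 59.3 normalised tags and 29.5-fold over input. This site had no R1881 H3T11P peak, but it overlapped a WDR5 peak of each treatment. The vehicle WDR5 peak lay at 59348108 to 59348308 (25.2 normalised tags) and the R1881 one at 59347884 to 59348102 (71.5). These WDR5 peaks did not overlap each other. The vehicle H3T11P list continued with chromosome 4, 8960957 to 8962190 (40.7 normalised tags, 4.67-fold), and chromosome 10, 1271570 to 1272329 (26.9 normalised tags, 4.45-fold). With R1881, the region with the most tags spanned 6324 bp of chromosome 1, 226809386 to 226815710, with 333.6 normalised tags over its length. Next came chromosome 17, 28173426 to 28174210 (220.8 normalised tags over only 784 bp), and chromosome 1, 159705458 to 159708848 (209.2 normalised tags over 3390 bp). All 3 of these R1881 regions were only 4.30- to 4.48-fold over input, and they held 58.2 to 94.3 scaled input tags, against a median of 2.3 over the list. None of them overlapped a WDR5 peak or a vehicle H3T11P peak, and with fold values this close to the caller's minimum of 4 their absence from the vehicle list shows no change.

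The second comparison asked where WDR5 was bound with and without androgen. The R1881 list held 4180 WDR5 peaks and the vehicle list 836, a ratio of 5.0. In contrast to H3T11P, most vehicle WDR5 sites were found again: 548 of 836 (65.6%, interval 62.2 to 68.8) overlapped an R1881 WDR5 peak, where shifted lists gave a mean of 0.608 and at most 4. Recurrence was 52.1% (44.2 to 59.9) in the lowest quintile of vehicle peaks by tag count and 92.9% (87.9 to 96.3) in the highest. Within the vehicle list, 102 peaks (12.2%) carried 20 or more normalised tags, and within the R1881 list 150 (3.59%). Seen from the R1881 list, 3632 peaks had no vehicle counterpart. Those 3632 had a median of 8.4 normalised tags, against 12.9 for the 548 R1881 peaks that did. The vehicle list reached 3.11% of the lowest quintile of R1881 peaks and 40.9% of the highest.

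The R1881 WDR5 library held 1.49 times the tags of the vehicle library, and the ratio of list lengths moved when depth was taken into account. It was 2.94 after the R1881 peaks were thinned to the vehicle depth, and 2.36 (1977 against 836 peaks) at a common peak score of 9.25 per 10000000 tags. Both alternatives adjust for depth only, and they removed R1881 peaks only, so they could only lower this ratio. In the headers, WDR5 peaks took 0.44% of all tags with R1881 and 0.11% with vehicle. A weaker immunoprecipitation in the vehicle WDR5 library was not tested, and with 1 library per treatment it cannot be told apart from androgen.

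The strongest WDR5 sites were occupied in both treatments. Chromosome 17, 19032036 to 19032236, held 64.7 normalised tags with vehicle, and the R1881 peak at 19032046 to 19032264 held 93.4, the highest of its list. Chromosome 11, 62365600 to 62365800, was the tallest vehicle site with 86.6 normalised tags, and its R1881 counterpart held 81.1. The third vehicle site, chromosome 16, 2257871 to 2258071, held 57.2 normalised tags, and its R1881 counterpart held 65.3. Unlike the sites on chromosomes 17 and 11 just named, it also lay in an R1881 H3T11P region, of 1661 bp. The next R1881 sites were chromosome 19, 3936224 to 3936442 (91.8 normalised tags, 145.3-fold over input), and chromosome 17, 18906068 to 18906286 (87.8 normalised tags, 139.1-fold). Their vehicle counterparts held 49.6 and 51.3 normalised tags. The site at 18906068 overlapped an R1881 H3T11P region of 15.7 normalised tags.

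The third comparison placed WDR5 against H3T11P. With R1881, 1724 of 4180 WDR5 peaks (41.2%, interval 39.7 to 42.8) overlapped an H3T11P peak, 68.0 times the mean of the shifted lists (0.606%, highest 1.05%). These sites made up 10.2% (9.73 to 10.7) of the R1881 H3T11P list. With vehicle, 7 of 836 WDR5 peaks (0.837%, 0.337 to 1.72) overlapped a vehicle H3T11P peak, where the shifts gave a mean of 0.0758% and at most 0.478%. Local shifts of 50 to 500 kb gave a mean of 3.02 overlaps and at most 9, and 7 of 1000 such shifts were at least as high as the 7 observed. Under the same local shifts, the R1881 lists gave a mean of 55.7 and at most 85 overlaps, against the 1724 observed. Yet the vehicle WDR5 peaks did lie where H3T11P was called with androgen: 292 of 836 (34.9%, 31.7 to 38.3) overlapped an R1881 H3T11P peak, against at most 1.67% in the shifts. Vehicle WDR5 peaks that recurred with R1881 did so in 42.0% of cases (37.8 to 46.2), and those that did not recur in 21.5% (16.9 to 26.7). The vehicle H3T11P list behind the 0.837% is the one with 83.8% of its peaks within 1 tag of the caller's threshold and 0.22% of its tags in peaks, against 57.8% and 2.17% for the R1881 list. With both lists held to at least 8-fold over input, the share of vehicle WDR5 peaks was 6.19% at R1881 H3T11P and 0.188% (1 of 533) at vehicle H3T11P.

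**Figure D2:**
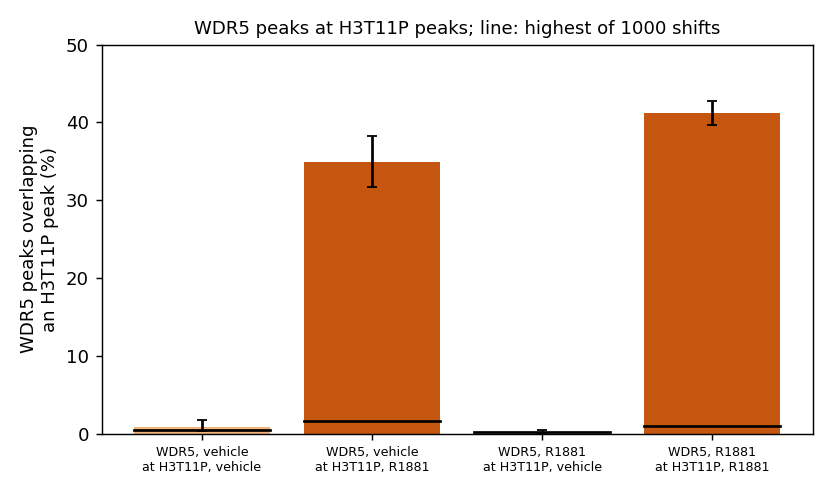
Share of WDR5 peaks (vertical axis, percent) that overlap an H3T11P peak, for each pair of lists, with 95% exact binomial intervals as error bars and the highest of 1000 shifted lists as a black line. Both WDR5 lists met the R1881 H3T11P list (34.9% and 41.2%) far above the shifts, and the vehicle H3T11P list in under 1% of peaks.

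H3T11P regions with more normalised tags held WDR5 more often. WDR5 was found at 1.8% (1.38 to 2.31) of the lowest quintile of R1881 H3T11P peaks by tag count and at 27.2% (25.7 to 28.7) of the highest. H3T11P regions with WDR5 had a median length of 708 bp and 16.5 normalised tags, and those without had 500 bp and 9.9. Their median fold over input was lower, 5.65 against 6.52, and they held more scaled input tags (mean 3.95 against 2.26). WDR5 height made less difference: H3T11P was found at 39.2% (35.9 to 42.6) of the lowest quintile of R1881 WDR5 peaks and at 40.4% (37.1 to 43.8) of the highest. The overlap of the R1881 lists depended on the cut on fold or p over input. The 8-fold cut is not a cut on tag count, since the H3T11P regions with WDR5 held more tags but had the lower fold. It also shortened the R1881 H3T11P list from 16677 to 4957 peaks, and shifts of these lists at that cut are not given here. The overlap was 10.4% of WDR5 peaks (251 of 2403), and 5.02% of H3T11P peaks, when both lists were held to at least 8-fold over input. It was 24.1% of WDR5 peaks at a p over input of at most 1e-10.

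**Figure D3:**
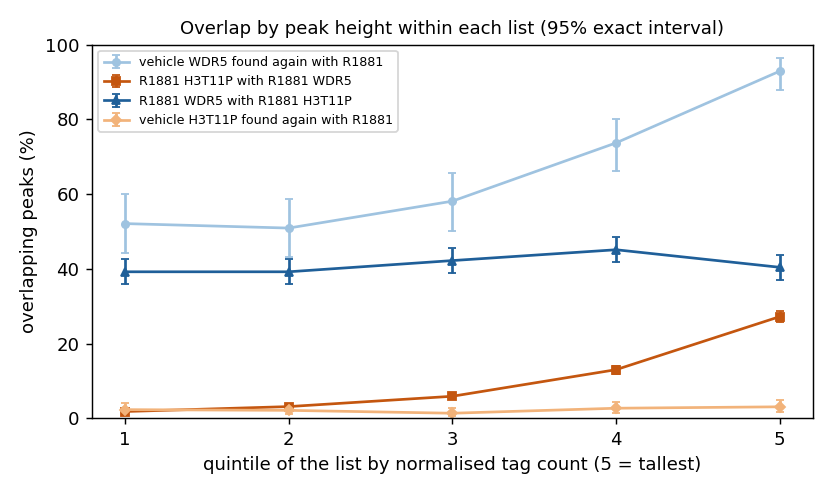
Share of peaks overlapping another list (vertical axis, percent) by quintile of the list, ranked by the authors' normalised tag count (horizontal axis, 5 is the tallest), with 95% exact binomial intervals. Recurrence of vehicle WDR5 peaks went from 52.1% to 92.9%, whereas that of vehicle H3T11P peaks stayed between 1.34% and 3.06%. The vehicle H3T11P peaks differed little in height below the highest quintile (5.5 to 9.0 normalised tags).

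WDR5 sites seen only with R1881 and those present in both treatments had similar shares at H3T11P when pooled over all heights. Of 3632 R1881-only WDR5 peaks, 1490 (41.0%, interval 39.4 to 42.6) overlapped an R1881-only H3T11P peak. Of the 548 R1881 WDR5 peaks with a vehicle counterpart, 227 (41.4%, 37.3 to 45.7) did. The difference was -0.4 percentage points, with a 95% Newcombe interval from -4.86 to 3.96. The classes differed in height, and when the R1881 WDR5 list was split in 3 by tag count, the shares of R1881-only and shared sites were 39.0% (36.3 to 41.6) and 45.8% (31.4 to 60.8) in the lowest, 41.6% (38.9 to 44.3) and 51.2% (40.0 to 62.3) in the middle, and 43.1% (40.0 to 46.3) and 38.9% (34.2 to 43.8) in the highest. The intervals overlapped at each height, and the order of the classes was not the same throughout. Leaving the vehicle H3T11P list out of the definition gave 41.2% and 41.8%. Under at least 8-fold over input the shares were 10.7% and 8.39%.

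R1881 peaks of both kinds, with no vehicle peak of either, coincided at 1478 WDR5 peaks and 1453 H3T11P regions. All joint sites of the R1881 lists numbered 1724 WDR5 peaks and 1698 H3T11P regions. In the whole R1881 lists, 3632 of 4180 WDR5 peaks and 16617 of 16677 H3T11P peaks had no vehicle peak of the same antibody. Absence from the vehicle lists is thus the usual case and not a trait of the joint sites. Ranked by WDR5 tag count, the first lay on chromosome 17 at 26445684 to 26445902, with 27.0 normalised WDR5 tags (21.4-fold over input), and its H3T11P region from 26445800 held 18.1. The second, chromosome 1 at 143920400 to 143920618, held 24.2 WDR5 and 43.7 H3T11P tags, with 12.3 scaled input tags in the H3T11P region. The third, chromosome 12 at 51584932 to 51585150, held 20.3 WDR5 and 9.9 H3T11P tags. On chromosome 3, the sites at 196869815 and 41215719 held 19.7 and 19.1 WDR5 tags and lay in H3T11P regions of 1320 and 915 bp. The sites at 137396520 and 180606083 of chromosome 5 held 19.1 and 16.3 WDR5 tags. On chromosome 10, the sites at 3817676 and 81955202 held 17.5 WDR5 tags each, in H3T11P regions of 1518 and 500 bp. The tenth site, chromosome 14 at 34943555, held 16.3 WDR5 tags within an H3T11P region of 1556 bp. Over the 10 sites, fold over input was 6.39 to 27.6 for WDR5 and 4.24 to 5.74 for H3T11P. With H3T11P fold values this close to the caller's minimum of 4, absence from the vehicle H3T11P list shows no change.

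The chromosomes contributed differently to the lists. Chromosome 19, the most gene-dense human chromosome, held 5.55% (5.21 to 5.91) of R1881 H3T11P peaks and 2.03% (1.52 to 2.65) of vehicle ones. Chromosome 17 held 6.47% (6.1 to 6.85) against 3.1% (2.47 to 3.84), and chromosome 16 held 5.43% (5.09 to 5.78) against 3.29% (2.64 to 4.05). Chromosome 22 held 1.85% (1.65 to 2.07) against 0.574% (0.322 to 0.945), and chromosome X 0.756% (0.63 to 0.899) against 0.191% (0.0622 to 0.446). Several chromosomes went the other way. Chromosome 1 held 13.3% (12.8 to 13.9) of R1881 and 18.9% (17.4 to 20.5) of vehicle H3T11P peaks, chromosome 3 held 5.34% (5.01 to 5.69) and 7.39% (6.41 to 8.46), chromosome 4 held 3.62% (3.34 to 3.92) and 5.74% (4.88 to 6.7), and chromosome 5 held 4.94% (4.62 to 5.28) and 6.2% (5.31 to 7.2). Chromosome Y, with 33 R1881 and 25 vehicle H3T11P peaks, held 0.198% (0.136 to 0.278) and 0.957% (0.62 to 1.41). For WDR5, chromosome 19 held 5.24% (4.58 to 5.96) with R1881 and 4.67% (3.34 to 6.32) with vehicle, and chromosome 17 held 6.94% (6.19 to 7.75) and 8.37% (6.59 to 10.5), so these intervals overlapped. Chromosome 16 held 4.93% and 5.74%. Chromosome 1 held 12.3% (11.3 to 13.4) of R1881 WDR5 peaks and 16.3% (13.8 to 18.9) of vehicle ones.

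**Figure D4:**
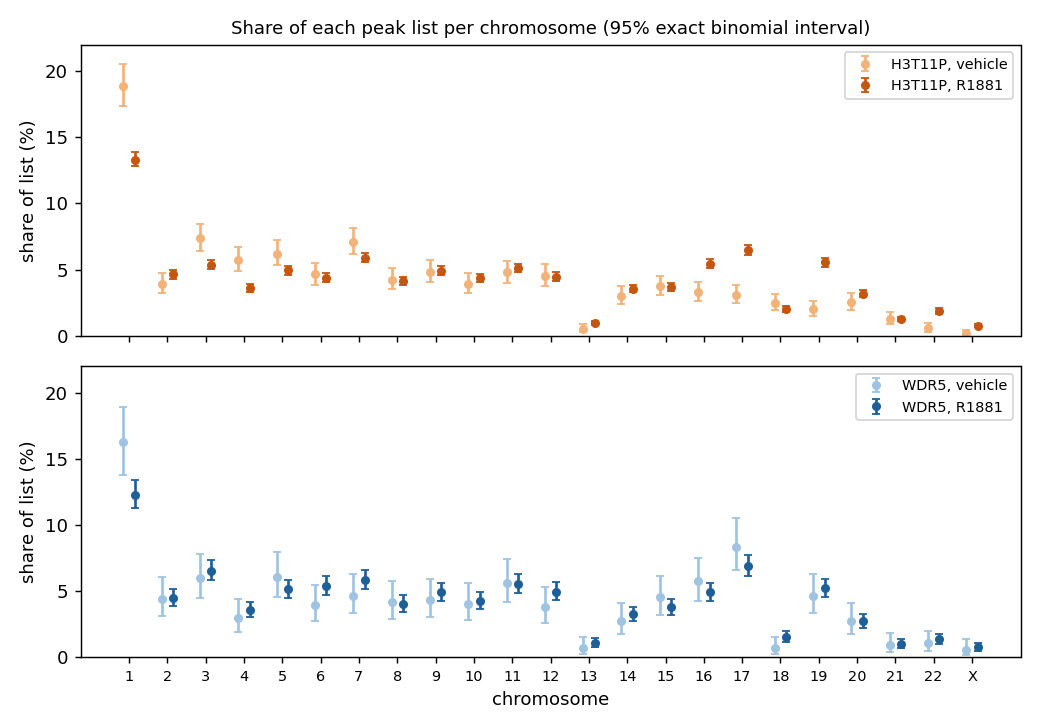
Share of each list (vertical axis, percent) on chromosomes 1 to 22 and X (horizontal axis), H3T11P above and WDR5 below, with 95% exact binomial intervals. Chromosome 19 holds 2.03% of the vehicle H3T11P list and 4.67% to 5.55% of the other lists, and chromosome 1 holds 18.9% and 16.3% of the vehicle lists and 13.3% and 12.3% of the R1881 lists.

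The densest 1 Mb windows of the R1881 H3T11P list were 0 to 1 Mb of chromosome 16 and 1 to 2 Mb of chromosome 19, with 61 peaks each, followed by 77 to 78 Mb of chromosome 17 with 60. The vehicle list held 0, 2 and 0 peaks there, and the R1881 WDR5 list 12, 11 and 15. The densest vehicle H3T11P window was 147 to 148 Mb of chromosome 1, with 13 peaks. That window also held 34 R1881 H3T11P peaks, 7 vehicle WDR5 peaks and 6 R1881 WDR5 peaks. The R1881 WDR5 list was densest at 130 to 131 Mb of chromosome 9, with 18 peaks against 5 with vehicle.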

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

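The tests of depth, by local shifts, by shifts of the R1881 list, of the number of libraries, of input tags at recurring H3T11P peaks, of the matched input tags, and of input tags on chromosome 1 without a limit on input were chosen after the overlaps or results they bear on had been seen. The tests of input tags at taller R1881 peaks of chromosome 1 and at vehicle WDR5 peaks were set down before their values were seen.

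Input tags, which measure background and entered the comparisons above only as such, stood out at the R1881 H3T11P regions with the most tags. The region at chromosome 1, 226809386 to 226815710, held 94.3 scaled input tags, or 14.9 per kb where the list's median was 3.06. It was 1 of 6 regions with 10 or more input tags between 226809386 and 226849252. A further 5 lay between 159676455 and 159708848 of the same chromosome, with 32.2 to 58.2 input tags. With so much input, the regions of both clusters passed the caller's requirement of 4-fold over input only narrowly, at 4.01- to 5.05-fold. In all, 160 R1881 H3T11P peaks had 10 or more input tags, against 1 vehicle peak. Under that 4-fold requirement, only peaks with many tags can hold so much input. The vehicle list held 7 peaks of 20 or more normalised tags and the R1881 list 1921, so the contrast does not measure background.

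The first pattern weighed is that only 60 of 2612 vehicle H3T11P peaks were found again with R1881. Lower depth argues the wrong way, since the vehicle library held 1.2 times the tags of the R1881 library. The 60 overlaps, above the 51 that the highest of 1000 local shifts gave (mean 31.7), argue against a vehicle list whose positions recur only by chance. Among peaks at least 8-fold over input there were 3 overlaps, where local shifts gave a mean of 2.29 and at most 10. That count is too low to tell a modest excess from chance, so it does not settle the question either way. Nor do the 60 show sites of H3T11P, since background shared by both libraries is a candidate explanation of them: input tags per kb were 1.15 times as high at the 60 vehicle peaks as at the others (95% bootstrap interval 1.02 to 1.28), and 1.34 times (1.17 to 1.55) at the R1881 peaks they overlapped. The androgen treatment itself, and a weaker immunoprecipitation in the vehicle library, cannot be told apart with 1 library per treatment.

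The second pattern is the crowding of vehicle H3T11P peaks on chromosome 1 above 125 Mb, with 371 peaks against 123 below (ratio 3.02), where the R1881 list had a ratio of 1.52 and the WDR5 lists 1.57 with vehicle and 1.16 with R1881. More DNA copies or background reads there are a candidate explanation. Over all vehicle H3T11P peaks of chromosome 1, input tags per kb were 1.15 times as high above 125 Mb as below (95% bootstrap interval 1.05 to 1.26), and at R1881 H3T11P peaks with 20 or more normalised tags 1.47 times (1.31 to 1.64), or 1.26 times (1.15 to 1.38) when peaks with 10 or more input tags were left out, a limit that was not part of the test as set down. The ratio was 1.13 (1.08 to 1.18) over all R1881 H3T11P peaks, 1.26 (1.13 to 1.41) over R1881 WDR5 peaks and 1.01 (0.82 to 1.26) over vehicle WDR5 peaks, which were called against the input of the same treatment as the crowded list. Peaks were called at a minimum fold over input, so input at peaks is not a free measure of background, and whether a difference of this size accounts for the crowding was not tested, nor was any biological explanation.

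The third pattern is that vehicle WDR5 peaks lay at H3T11P regions of the R1881 library (34.9%) and seldom at those of the vehicle library (0.837%). Chance hits on the longer R1881 list are argued against as the source of the 34.9%, since the highest of 1000 shifts of it gave 1.67%. The highest of 1000 local shifts gave 27 of 836 peaks, against the 292 observed. The shifts do not test how far list length feeds the contrast with 0.837%. Per H3T11P peak, 1.74% of the R1881 list (291 of 16677) and 0.268% of the vehicle list (7 of 2612) met a vehicle WDR5 peak. DNA that is recovered more easily whatever the antibody stays open: input tags at vehicle WDR5 peaks with an R1881 H3T11P region were 0.981 times those at the other peaks (95% bootstrap interval 0.89 to 1.08), an interval that holds both higher and lower input. A different set, R1881 H3T11P peaks of 500 bp with an R1881 WDR5 peak, had 1.1 times the R1881 input tags (1.07 to 1.13) of peaks with equal tags without one, which does not bear on the vehicle WDR5 peaks directly. The androgen treatment stays open too, as does a weak immunoprecipitation in the vehicle H3T11P library (0.22% of tags in peaks against 2.17%), which would leave few peaks for WDR5 to meet, and neither was tested, since there is 1 H3T11P library per treatment.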

How the results depend on the processing

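Of 102 alternative values, 57 stayed within the main value's interval (or within 1.5 times a ratio of peak numbers), 45 moved and 0 reversed. Most of these values are single shares, which have no direction to reverse. The order of R1881-only and shared WDR5 sites at H3T11P was not scored, and it did change. The shares were 41.0% and 41.4% in the main setting, and 10.7% and 8.39% at 8-fold over input. At a p of at most 1e-10 they were 24.8% and 19.7%, and the intervals overlapped each time. The common minimum tag count left 2611 of 2612 vehicle H3T11P and 4117 of 4180 R1881 WDR5 peaks, so it tests little. The R1881 list stayed the longer one for both antibodies under every alternative run. For H3T11P, thinning and the common score removed vehicle peaks only, so neither could make the R1881 list the shorter one. With 1 library per group, no paired analysis or leaving out of a replicate was possible. Removing unplaced contigs tests nothing, as the lists hold 0 such peaks. The 57 include every value of this and the common minimum, which could hardly move. Promoter shares and gene lists were not run. Thinning, the common peak score, the p of 1e-10, local shifts and leaving out the vehicle H3T11P list were chosen after seeing the data. Within 1 tag of the caller's threshold lay 83.8% of vehicle and 57.8% of R1881 H3T11P peaks, and 48.4% of vehicle and 29.8% of R1881 WDR5 peaks.

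The ratio of H3T11P peak numbers (main 6.38) was 39.5 at a common score per 10000000 tags (16677 against 422 peaks), 12.0 after thinning and 12.0 at a p of at most 1e-10. By construction, the common score removed most vehicle peaks because they sat at a lower threshold per tag sequenced. The WDR5 ratio (main 5.0) was 2.36 at a common score and 2.94 after thinning. For the other moved values below, the cause was not tested.

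At least 8-fold over input, recurrence of vehicle peaks was 0.329% for H3T11P and 53.7% for WDR5, and the shared part of the R1881 lists was 0.0605% and 11.9%. WDR5 peaks at H3T11P were 0.188% with vehicle and 10.4% with R1881 (5.02% of the H3T11P list), 6.19% for vehicle WDR5 at R1881 H3T11P, 10.7% for R1881-only WDR5 and 8.39% for WDR5 in both treatments. Chromosome 1 held 15.9% of vehicle and 11.1% of R1881 H3T11P peaks, and chromosome 16 held 5.0% of R1881 ones.

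At a p over input of at most 1e-10, recurrence of vehicle H3T11P peaks was 0.275%, and the shared part of the R1881 lists was 0.023% for H3T11P and 14.9% for WDR5. WDR5 peaks at H3T11P were 0.267% with vehicle and 24.1% with R1881 (8.99% of the H3T11P list), 17.3% for vehicle WDR5 at R1881 H3T11P, 24.8% for R1881-only WDR5 and 19.7% for WDR5 in both treatments.

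Requiring an overlap of 50% of the shorter peak gave a recurrence of 1.53% for H3T11P and 56.0% for WDR5 (0.24% and 11.2% of the R1881 lists), and 37.5% of R1881 WDR5 peaks at H3T11P (9.29% of the H3T11P list), 30.6% of vehicle WDR5 peaks at R1881 H3T11P and 37.4% of R1881-only WDR5. Centres within 1 kb gave 3.64% and 70.7% (0.576% and 14.3% of the R1881 lists), 48.7% (12.0% of the H3T11P list), 44.7% and 48.3% for the same quantities in the same order, and 50.3% for WDR5 in both treatments. The chance share of WDR5 at H3T11P under local shifts was 1.32% with R1881 and 0.354% with vehicle, against 0.606% and 0.0758% when shifted along whole chromosomes. These local shifts are a separate set of random draws from those in the Results, whose means were 1.33% and 0.361%.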

Other observations

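Around WDR5, H3T11P of the R1881 list was concentrated at short range. With R1881, 50.5% of WDR5 peak centres lay within 1 kb of an H3T11P region, 56.3% within 5 kb and 62.1% within 10 kb, where 200 shifts gave means of 1.83%, 6.72% and 11.9%. For vehicle WDR5 peaks against the R1881 H3T11P list the shares were 47.1%, 55.9% and 62.4%, with shift means of 1.97%, 6.98% and 12.3%. Against the vehicle H3T11P list they were 1.56%, 4.31% and 6.58%, with shift means of 0.245%, 1.11% and 2.11%. For R1881 WDR5 peaks against the vehicle H3T11P list they were 0.718%, 2.3% and 4.0%, with shift means of 0.248%, 1.04% and 2.0%.

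Beside the sites overlapping the R1881 H3T11P list, 461 R1881 WDR5 peaks (11.0%) had no R1881 H3T11P peak of their own but 1 or more R1881 regions on a single side within 2 kb, and 31 (0.742%) lay between regions on both sides. For vehicle WDR5 peaks, set against the same R1881 H3T11P list, the counts were 136 (16.3%) and 7 (0.837%). H3T11P peaks were stitched into regions by the caller, which limits how often a WDR5 peak can lie between regions.

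A single vehicle WDR5 peak overlapped peaks of the other 3 lists.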
